A study of Mus musculus with 10 samples.

How the data were processed

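Ventricle RNA of 10 male mice, 5 untreated and 5 given aldosterone for 7 days, had been hybridised in Cy5 to 2-colour Agilent arrays against a pooled tissue reference in Cy3, per the labels. Each sample is labelled as a separate mouse. The deposited scanner files hold spot intensity values for 9 arrays, read with Agilent Feature Extraction 10.7.3.1, per the file headers. Their log ratio column is on a log10 scale of Cy5 over Cy3, per the file headers, and was used after conversion to log2. The authors' deposited value table holds a log2 ratio per probe for all 10 samples. For the 9 arrays at hand it was the scanner's log ratio on the log2 scale, averaged per probe, with Pearson correlations from 0.996 to 1.00 over probes and a slope of 1.00, and 82.7% to 86.6% of probes agreed within 0.001. Scale and direction were therefore known, no centring was seen, and the column medians were 0.06, 0.06, 0.12, 0.02 and 0.02 for controls 1 to 5 and 0.04, 0.08, 0.11, -0.01 and 0.04 for aldosterone 1 to 5. How the remaining probes differ is not given in the sources used here.

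The design planned the mean signals and the gene name column of the scanner files. The files used here hold median signals and an accession per probe, so median signals with the median local background were used. Accessions without versions were matched to RefSeq gene records of the GRCm38.p6 mouse assembly, which named 26581 of 39429 probes for 20144 genes, and 12848 probes kept the file's own name. No coordinates are given.

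Intensities were background-corrected with normexp and an offset of 50, and log2 ratios were normalized by loess within each array, with control spots at weight 0 (R 4.3.3, limma 3.58.1). Control spots were left out, as were 1667 other spots over all arrays that were marked as outliers. Spots of 1 probe were averaged, from 43020 spots to 39429 probes. A probe was kept if its Cy5 signal was well above background on at least 4 arrays, which left 26871, and each gene was represented by its probe of highest mean signal, chosen without regard to group. This gave 22011 genes or transcripts, 15226 of them with a symbol. Of 4089 genes with more than 1 probe kept, 1497 had a probe of opposite sign. Among the genes named here this held for Gpbp1l1, Polr3gl, Birc5 and Slc25a37.

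The comparison was a limma linear model with empirical Bayes variances on 5 control and 4 aldosterone arrays, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 29 gene lists of pathways and cell type markers were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and the list means per array with an exact permutation of the 126 splits of the arrays. Named genes followed a rule fixed at the same time. It took the genes of largest change that passed, or the 8 of smallest p per direction where fewer than 6 passed, the 4 members of smallest p in each list that passed, and a fixed set of steroid-responsive, cardiac and matrix genes. Values of 4 genes that the rule names are not reported here. On simulated data with 200 of 21973 genes changed, the fit recovered 43.5% of changes of 0.5, 84.5% of changes of 1 and 98% of changes of 2 on the log2 scale. The simulated noise had each gene's own spread but was normal and independent between genes. It held no sets of hearts such as those described below, so these shares need not hold for the real arrays.

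Controls and aldosterone arrays shared each of 4 slides, and each slide was scanned at 1 time, so slide and scan are 1 batch. Slide 1 held 2 controls. The hearts also fell into 2 sets that cross the groups, described below. On slides 2 and 4 the control and the aldosterone array came from different sets, so differences within these slides mix set and treatment. On slide 1, control 1 came from a different set than control 2 and the aldosterone array, so its difference carries the set in part. Slide 3 alone held arrays of a single set. Position on the slide followed the group, with controls at positions 1 or 4 and aldosterone arrays at position 2, so position and group cannot be told apart.

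On control 1 a few spots had extreme local backgrounds, up to 11739.5 units in Cy5, against at most 712 on any other array. They set the noise term of its normexp model to an SD of 193 units in Cy5, where the other arrays had 0.866 to 16.2. The planned values were kept as the main result. An alternative chosen after seeing the data replaced local backgrounds more than 20 units from the array's median by that median. It did so for 41 Cy5 and 8 Cy3 spots of control 1, 7 Cy3 spots of aldosterone 1 and 0 to 85 Cy5 spots of each other array.

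Other ways of processing and testing, fixed before the data were examined, were no background correction, an offset of 16, Agilent processed signals, median centring, Aquantile or scale normalization after loess, the Cy5 channel alone, 3 other filters on dim probes, outlier spots kept, slide as a fixed or random block, replicate number as a block, array weights, a trended robust variance, the deposited value table with 9 or 10 samples, each array left out in turn, every probe tested, an adjusted p threshold of 0.1, and an unadjusted p with a 1.5-fold difference. The Cy3 channel alone served as a negative control.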

Results

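The series profiled ventricle RNA of male mice that were untreated or had received aldosterone, the adrenal steroid that acts through the mineralocorticoid receptor, over 7 days. Each of 10 hearts was labelled with Cy5 and hybridised to a 2-colour Agilent mouse array against 1 common reference labelled with Cy3, a mix of RNA from brain, kidney, liver, spleen and heart. There were 5 control hearts and 5 aldosterone hearts, each from its own animal. Scanner files of 5 control and 4 aldosterone arrays were analysed, and aldosterone replicate 4 entered through the deposited value table alone. Between 25348 and 27953 of 39429 probes were well above background in Cy5 on an array, or 64.3% to 70.9%. The median Cy5 signal of an array lay between 118.5 and 146.25 units, over a median local background of 57 to 59 units. All differences are aldosterone minus control on the log2 scale, and the comparison addressed which cardiac genes respond to aldosterone.

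In the aldosterone group, fibroblast markers, extracellular matrix genes, cell cycle genes and hypertrophy genes shifted up as lists in a test with a preset correlation between members, by means of 0.27, 0.25, 0.22 and 0.29. None of the 4 passed with an estimated correlation (adjusted p = 0.317, 0.317, 0.793 and 0.317). The lists of lymphocyte, interferon response, adipocyte, oxidative stress and circadian clock genes shifted down, and that of red blood cell markers shifted up. The lymphocyte and interferon response shifts depended on single arrays, as given below. No single gene passed adjustment over all genes. The fit held no term for the sets of hearts described below, so their differences count as spread within the groups. A lack of calls therefore does not show a lack of response. In camera, a test of a list against all other genes with a preset correlation between members, 10 of the 29 lists passed at an adjusted p under 0.05. With a correlation estimated from the arrays, 0 of the 29 passed and 3 had an unadjusted p under 0.05, with the smallest adjusted p, 0.317, shared by the fibroblast, matrix and hypertrophy lists.

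Fibroblast markers rose as a list, with 19 of 21 measured members higher in the aldosterone group (camera adjusted p = 3.84e-11; adjusted p = 0.317 with an estimated correlation). The mean over members was 0.30 ± 0.16 in controls (SD, n = 5) and 0.57 ± 0.16 with aldosterone (SD, n = 4). No member passed over all genes, and 5 passed when adjusted over the list alone. The intermediate filament gene Vim differed by 0.46 (SE 0.10), Pcolce, an enhancer of procollagen processing, by 0.35 (SE 0.09), the growth factor receptor gene Pdgfra by 0.27 (SE 0.08) and the microfibril gene Mfap5 by 0.48 (SE 0.14). An exact two-sided permutation test of the arrays gave p = 0.0476 for the list mean, and adjusted p = 0.46 over the 29 lists. The smallest p this design allows is 0.00794. The shift was 0.29 with slide as a block, and within the 4 slides it was 0.33, 0.16, 0.38 and 0.28. On slides 2 and 4 the control and aldosterone arrays came from different sets of hearts, described below, so those values also carry the set. The value of slide 1 carries it in part, as control 1 came from a different set than control 2 and aldosterone 1. The list mean was 0.17 on control 1, 0.55 on control 2 and 0.69 on aldosterone 1.

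Extracellular matrix and fibrosis genes rose as a list too, with 24 of 29 measured members higher (camera adjusted p = 1.79e-10; adjusted p = 0.317 with an estimated correlation). None passed over all genes, and 3 passed adjusted over the list alone, namely the basement membrane collagen gene Col4a1 (0.41, SE 0.09) and the collagen crosslinking enzyme genes Loxl1 (0.52, SE 0.12) and Loxl2 (0.53, SE 0.14). Col6a1 differed by 0.36 (SE 0.11). The fibrillar collagen genes Col1a1 and Col3a1 differed by 0.54 (SE 0.22) and 0.55 (SE 0.24), both with an adjusted p of 1 when rounded. The profibrotic factor gene Ccn2 differed by 0.24 (SE 0.22). The shift was 0.28 with slide as a block, and 0.34, 0.07, 0.43 and 0.27 within the 4 slides. The exact permutation p of the list mean was 0.0556. Col1a1, Col1a2 and Col3a1 belong to both this list and the fibroblast list, so their shifts are not independent results.

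The other cell types of the ventricle wall gave smaller values. Endothelial markers differed by a mean of 0.04 (camera adjusted p = 0.313), smooth muscle and pericyte markers by 0.01 (0.962) and cardiomyocyte markers by -0.02 (0.441). The fibroblast mean exceeded the average of the endothelial and smooth muscle means by 0.25 more with aldosterone than in controls (exact permutation p = 0.0238). This comparison was not planned, was chosen after the data were seen, and its p is unadjusted. The fibroblast list alone had an exact permutation adjusted p of 0.46.

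Proliferation genes rose as a list, with 24 of 27 measured members higher and a mean shift of 0.22 (camera adjusted p = 1.1e-07; adjusted p = 0.793 with an estimated correlation). No member passed over all genes and 2 passed adjusted over the list alone. These were Mcm6, a subunit of the helicase that opens replication origins (0.87, SE 0.12), and the proliferation marker Mki67 (0.67, SE 0.16). Birc5 and Ccna2, which act in mitosis, differed by 0.50 (SE 0.19) and 0.49 (SE 0.22). One array, control 1, set much of the spread. With its stray local backgrounds replaced, an alternative chosen after seeing the data, the mean shift was 0.36 and 20 members passed adjusted over the list alone. The exact permutation p was then 0.00794, the smallest possible, against 0.214 before, but the adjusted p over the lists was 0.115, and adjusted p = 0.136 was found with an estimated correlation. All 4 aldosterone arrays then lay above all 5 controls. Under the planned normalization the shift was 0.26 with slide as a block, and 0.26, 0.35, 0.27 and 0.16 within the 4 slides. With the stray backgrounds replaced it was 0.57, 0.35, 0.28 and 0.16 within the slides.

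**Figure D1:**
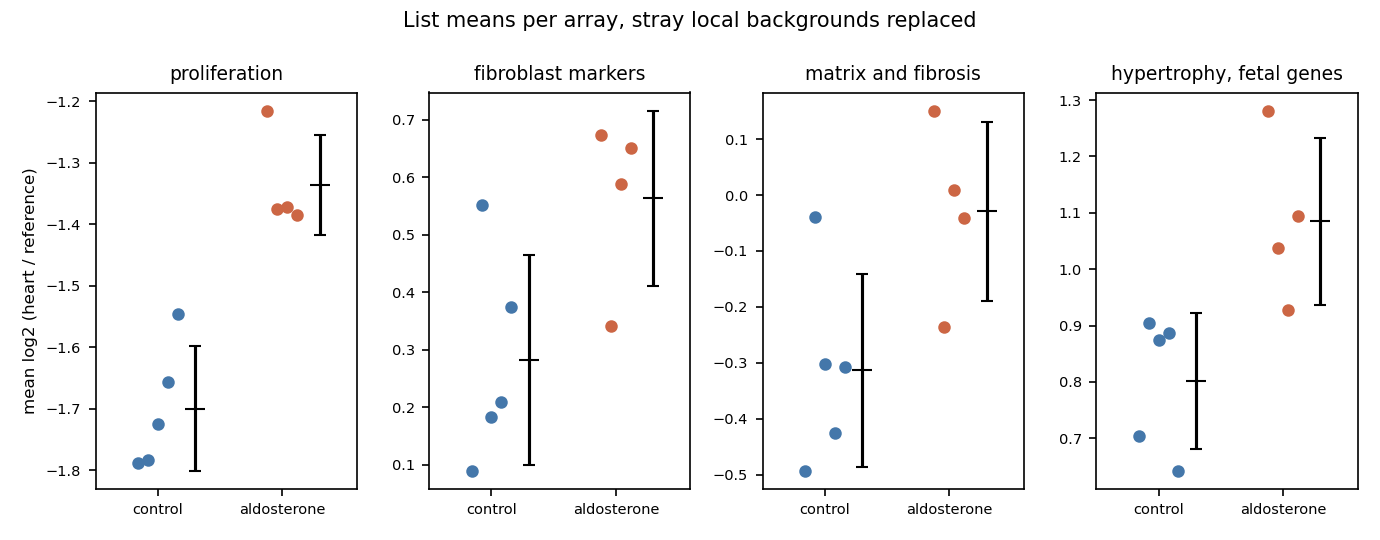
Mean log2 ratio of heart over reference for 4 gene lists, after replacement of stray local backgrounds; each point is an array, 5 control and 4 aldosterone, and bars give the group mean and SD. For proliferation the aldosterone arrays lie between -1.38 and -1.22 and the control arrays between -1.79 and -1.55, while for fibroblast markers the groups overlap.

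Hypertrophy and fetal cardiac genes rose as a list, with 14 of 16 measured members higher and a mean shift of 0.29 (camera adjusted p = 1.21e-05; adjusted p = 0.317 with an estimated correlation). Its mean was 0.80 ± 0.12 in controls (SD, n = 5) and 1.09 ± 0.16 with aldosterone (SD, n = 4). The exact permutation p was 0.00794 and its adjusted value over the lists 0.23. Csrp3, which encodes a muscle LIM protein of the Z-disc, was the 1 member to pass adjusted over the list alone (0.42, SE 0.07), and none passed over all genes. The natriuretic peptide genes Nppb and Nppa differed by 1.08 (SE 0.33) and 0.84 (SE 0.32), Ankrd1 by 0.43 (SE 0.20), the skeletal actin gene Acta1 by 0.62 (SE 0.39) and the slow myosin gene Myh7 by -0.33 (SE 0.36). Without control replicate 5, which had the lowest Ankrd1 and Acta1 and the highest Myh7 of the controls, Ankrd1 differed by 0.24 (SE 0.10), Acta1 by 0.25 (SE 0.18) and Myh7 by -0.02 (SE 0.22). The Cy5 spot was saturated for Nppa on 4 arrays, for Acta1 on 5 and for Ankrd1 on 3. The shift of the list was 0.30 with slide as a block, and 0.49, 0.16, 0.04 and 0.45 within the slides. With scale normalization after loess its call was lost.

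Red blood cell markers shifted up by a mean of 0.19, with 9 of 13 members higher (camera adjusted p = 0.0107; adjusted p = 0.793 with an estimated correlation). The beta globin gene Hbb-b2, whose Cy5 spot was saturated on 1 array, differed by 1.06 (SE 0.30), the erythroid heme synthesis gene Alas2 by 0.76 (SE 0.23) and the mitochondrial iron carrier gene Slc25a37 by 0.50 (SE 0.13), and they were among the 4 that passed adjusted over the list alone. This shift in a blood cell marker list moved in the same direction as those of the fibroblast, matrix, proliferation and hypertrophy lists. Within the slides it ranged from 0.00254 to 0.36, and with slide as a block it was 0.21. Leaving out aldosterone replicate 1 or the filter on dim probes ended the call. The median over members was 0.07, and the exact permutation p of the list mean was 0.302.

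Adipocyte markers shifted down by a mean of -0.17, with 11 of 14 members lower (camera adjusted p = 0.0112; adjusted p = 0.793 with an estimated correlation). None passed adjusted over the list alone, and Cfd, the adipokine adipsin, differed by -1.07 (SE 0.37), the lipase gene Lipe by -0.22 (SE 0.07), Plin4 by -0.16 (SE 0.10) and Cidec by -0.30 (SE 0.22). Cidec was well above background on 5 control and 2 aldosterone arrays. In the value table of all 10 hearts Cfd differed by -1.64 (SE 0.47), Lipe by -0.51 (SE 0.10), Plin4 by -0.13 (SE 0.08) and Cidec by -1.68 (SE 0.63). None of these passed over all genes. The circadian clock list shifted down by -0.08, with 13 of 18 members lower (camera adjusted p = 0.0362; adjusted p = 0.553 with an estimated correlation). Dbp and Nr1d1, a clock output factor and a clock repressor, differed by -0.39 (SE 0.13) and -0.43 (SE 0.17), Hlf by -0.27 (SE 0.16) and Npas2, well above background on 2 control and 3 aldosterone arrays, by -0.12 (SE 0.07). With slide as a block the 2 lists shifted by -0.14 and -0.08, and each was lower on 3 of the 4 slides. The adipocyte list had an exact permutation p of 0.159 for its mean and passed camera in 24 of 31 alternatives. Its call was lost without background correction (adjusted p = 0.0507), with both stricter filters on dim probes (0.0657 and 0.0962) and without control replicate 1 (0.0548), control replicate 2 (0.0528), aldosterone replicate 3 (0.0754) or aldosterone replicate 5 (0.141). Its mean ranged from -0.40 in the value table of all 10 hearts to -0.10 without control replicate 1. The circadian clock list had an exact permutation p of 0.0635 for its mean and passed camera in 17 of 31 alternatives. Its call was lost without background correction (adjusted p = 0.0511), with median centring (0.0992), in the value table of all 10 hearts (0.0779) and on leaving out 6 of the 9 arrays in turn, with adjusted p up to 0.197.

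Lymphocyte markers shifted down by -0.21, with 21 of 21 members lower, and interferon response genes by -0.22, with 28 of 29 lower (camera adjusted p = 0.000229 and 0.00055; adjusted p = 0.793 for both with an estimated correlation). No member of either list had an unadjusted p under 0.05 in limma, and the exact permutation p of the list means was 0.643 and 0.595. Both shifts depended on single arrays. Without control replicate 1 the lymphocyte shift was 0.00728 (camera adjusted p = 0.836), and without control replicate 2 the interferon shift was 0.000164 (camera adjusted p = 0.712). The interferon call was also lost without aldosterone replicate 1 (camera adjusted p = 0.121). With stray backgrounds replaced, the lymphocyte list mean of control 1 went from -1.17 to -2.16. The lymphocyte shift was then -0.06 (camera adjusted p = 0.0232, exact permutation p = 0.333). The T cell gene Cd3e differed by -0.14 (SE 0.11), Nkg7 by -0.14 (SE 0.08), Dntt by -0.15 (SE 0.10) and the granzyme gene Gzma by -0.44 (SE 0.36). Among the interferon genes, Usp18 differed by -0.35 (SE 0.19), Ifit3 by -0.38 (SE 0.24) and Ifi35 by -0.19 (SE 0.13). Oxidative stress genes shifted down by -0.10 (18 of 26 lower; camera adjusted p = 0.0333; adjusted p = 0.793 with an estimated correlation), with Txnip at -0.62 (SE 0.24), Gclc at -0.27 (SE 0.12), Nqo1 at -0.18 (SE 0.09) and Cyba at -0.16 (SE 0.09). The oxidative stress list had an exact permutation p of 0.357 for its mean and passed camera in 14 of 31 alternatives. Its call was lost with slide as a block (adjusted p = 0.0519), with stray backgrounds replaced (0.160), in the value table of all 10 hearts (0.742), without background correction (0.227), with median centring (0.0828) and without control replicate 1 (0.183), among others. With slide as a block the lymphocyte, interferon and oxidative stress lists shifted by -0.14, -0.17 and -0.07.

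Corticosteroid receptor targets did not pass as a list (mean 0.04, median -0.02; 15 of 32 higher; camera adjusted p = 0.532). They passed in 1 of 31 alternatives, without aldosterone replicate 5 (mean 0.12, camera adjusted p = 0.00953). The list mean followed 2 sets of hearts that cross the groups, described below. With stray backgrounds replaced it lay between -0.59 and -0.39 on controls 1, 3 and 4 and aldosterone 3 and 5. On controls 2 and 5 and aldosterone 1 and 2 it lay between -0.24 and -0.14. Among targets that the glucocorticoid and mineralocorticoid receptors share, Fkbp5 differed by -0.03 (SE 0.14), Sgk1 by 0.13 (SE 0.16), Per1 by -0.02 (SE 0.10), Tsc22d3 by 0.20 (SE 0.15), Zbtb16 by -0.18 (SE 0.24) and Lcn2 by -0.04 (SE 0.09). The chemokine gene Ccl2 differed by 0.09 (SE 0.15). The glucocorticoid receptor gene Nr3c1 and the mineralocorticoid receptor gene Nr3c2 differed by 0.13 (SE 0.08) and -0.03 (SE 0.08). All of these values had an adjusted p of 1 when rounded. The sign of Fkbp5 turned in 8 of 31 alternatives, that of Per1 in 6 and that of Lcn2 in 11. Hsd11b2, whose enzyme inactivates glucocorticoids, was well above background on 3 arrays at most and was not tested.

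Across all genes, limma called 0 of 22011 genes or transcripts at an adjusted p under 0.05, while 693 had an unadjusted p under 0.05 (445 higher, 248 lower), where 1101 would arise by chance. With stray backgrounds replaced 0 were called and 1365 had an unadjusted p under 0.05 (920 higher, 445 lower). The smallest adjusted p was 0.301, shared by the cyclin gene Ccnd1 (0.84, SE 0.11), Mcm6 and the membrane protein gene Emp1 (0.68, SE 0.10). Ccnd1 was -1.35 ± 0.05 in controls (SD, n = 5) and -0.51 ± 0.26 with aldosterone (SD, n = 4), a 1.79-fold difference. The other genes of smallest p on the higher side were Col5a3 (0.51, SE 0.08), the histone gene H2ac22 (0.47, SE 0.08), Csrp3, Pimreg (0.45, SE 0.08) and Adcy7 (0.60, SE 0.11). On the lower side they included Smim19 (-0.35, SE 0.07), H2-Ke6 (-0.33, SE 0.08), Gpbp1l1 (-0.33, SE 0.09), Polr3gl (-0.20, SE 0.06), Nudc (-0.40, SE 0.11), Isyna1 (-0.43, SE 0.12) and Echdc2 (-0.36, SE 0.10). Those named on the higher side were higher within each of the 4 slides, and on the lower side Nudc and Isyna1 were higher on 1 slide. As the genes were chosen by p on the same arrays, this is no separate test. None of these genes passed the test.

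**Figure D2:**
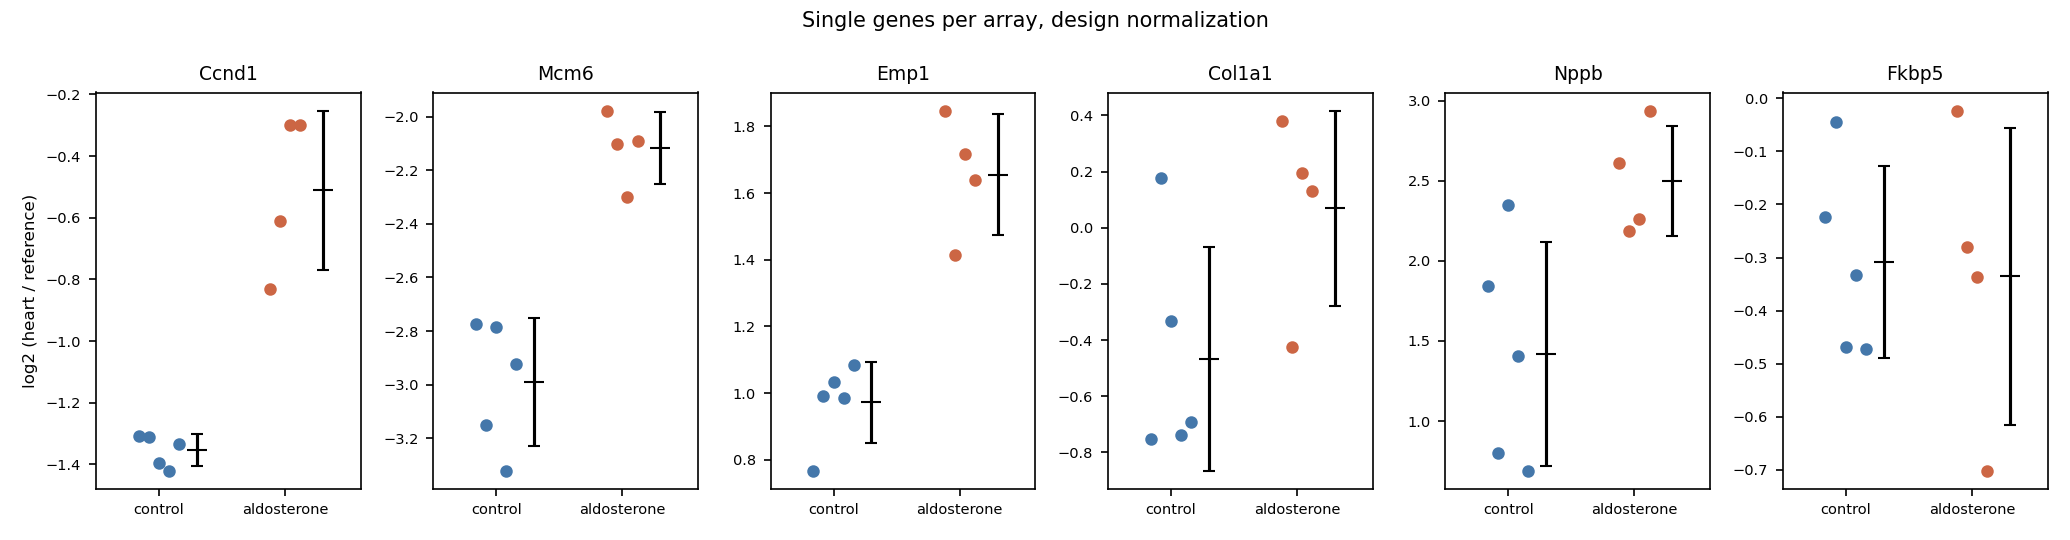
Log2 ratio of heart over reference for 6 genes after the planned normalization; each point is an array, 5 control and 4 aldosterone, and bars give the group mean and SD. Ccnd1, Mcm6 and Emp1, the 3 genes of smallest p, separate the groups, whereas Col1a1, Nppb and Fkbp5 overlap, and none of the 6 passed adjustment over all genes. Over all genes 1.19% separate the groups, and 2.10% with stray backgrounds replaced, where chance gives 1.59%.

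The scanner's own processed values gave more calls. In the deposited table of all 10 hearts, limma called 37 genes, 33 higher and 4 lower, with 1774 at an unadjusted p under 0.05. Of the 33, 9 belonged to the proliferation list, against 0.04 expected from its 27 members among the genes tested (Fisher's exact test, p = 5.32e-20). That test takes co-regulated genes as independent, and in the same table the proliferation list had a mean of 0.72, adjusted p = 0.0803 with an estimated correlation and an exact permutation adjusted p of 0.115. The 9 were Mcm6 (1.01, SE 0.15), Ccna2 (1.11, SE 0.16), Birc5 (0.83, SE 0.13) and, named after their values were seen, the mitotic kinase genes Cdk1 (0.99, SE 0.14), Plk1 (0.55, SE 0.08), Bub1b and Bub1 with the spindle genes Kif11 (0.94, SE 0.11) and Nusap1 (1.06, SE 0.17). Bub1 was well above background on 0 of 5 control arrays and 4 of 4 aldosterone arrays, and Bub1b on 1 and 4, so their ratios in controls are bounds. Under the planned normalization Kif11, above background on 3 of 5 controls, differed by 0.05 (SE 0.12), and Cdk1 and Nusap1, above background on all arrays, by 0.30 (SE 0.17) and 0.17 (SE 0.25). Ccnd1 (0.92, SE 0.12), Csrp3 (0.48, SE 0.06), Emp1 (0.63, SE 0.10) and Pimreg (1.56, SE 0.23) were called higher, and Smim19 (-0.38, SE 0.05) lower. Without aldosterone replicate 4 the same table gave 13 calls, of which 11 were among the 37, and without control 1 it gave 6, all among the 37. Under the planned normalization 36 of the 37 had the same sign. As that fit used 9 of the same 10 hearts, this is no separate test, and many of the differences were much smaller there.

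The other 15 lists that did not pass held no member past the threshold over all genes. Ion channels and transporters differed by a mean of 0.10 (camera adjusted p = 0.0536), skeletal muscle markers by 0.09 (0.197), immediate early genes by 0.06 (0.197), lung epithelial markers by -0.13 (0.197), monocyte and macrophage markers by 0.06 (0.274) and oxidative phosphorylation genes by -0.02 (0.313). Atrial and conduction markers differed by -0.02 (0.345), neutrophil markers by -0.06 (0.345), cytokines, chemokines and adhesion molecules by 0.04 (0.349), endoplasmic reticulum stress genes by -0.04 (0.435) and fatty acid oxidation genes by -0.04 (0.441). Mesothelial markers differed by -0.09 (0.581), corticosteroid and renin-angiotensin components by -0.05 (0.581), heat shock proteins by -0.03 (0.606) and glycolysis genes by a mean of -0.00393 (0.606; median 0.00682). Immediate early genes passed in 9 of 31 alternatives, among them stray backgrounds replaced (camera adjusted p = 0.0245), ion channels and transporters in 8 and oxidative phosphorylation genes in 6. The ion channel list mean followed the 2 sets of hearts described below. With stray backgrounds replaced it was 0.33 to 0.57 on controls 1, 3 and 4 and aldosterone 3 and 5, against 0.67 to 0.80 on the others. The monocyte and macrophage list passed in 6, among them slide as a block (mean 0.11, camera adjusted p = 0.0253), stray backgrounds replaced (0.13, 0.0451) and the value table of all 10 hearts (0.20, 0.00478).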

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

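All tests of explanations in this part were chosen after the result was seen, while the rule that picks out single samples was fixed beforehand. A sample was picked out where it stood apart from the other samples of its group by Dixon's ratio. Of 198 groups of values examined, 14 had such a sample, where chance gives 9.9.

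For genes, control 5 was low for Ankrd1 (1.56, nearest other control 2.49), control 2 was high for Ifit3 (-0.00364, nearest -0.93) and low for Hbb-b2 (-2.57, nearest -1.34), and control 1 was high for Dntt (-0.19, nearest -0.55). Aldosterone 1 was low for Ifit3 (-1.61, nearest -1.19). For list means, control 3 was low for oxidative phosphorylation (1.04, nearest 1.30) and control 2 was high for interferon response (-0.23, nearest -1.14). Aldosterone 1 was high for proliferation (-1.14, nearest -1.37), atrial and conduction markers (-1.51, nearest -1.71) and lung epithelial markers (-1.77, nearest -1.88). Control 1 was high for the list means of neutrophil markers (-3.12, nearest -4.11), lymphocyte markers (-1.17, nearest -2.19), mesothelial markers (-1.18, nearest -2.00) and lung epithelial markers (-1.37, nearest -1.74).

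Control 1 accounted for 5 of the 14, all of them high. Over all genes its log2 ratios deviated from the mean of the other arrays by a median of 0.18, against 0.09 to 0.13 on the other arrays. A sample that held reference RNA or other tissue would show the same rise in the scanner's own processed ratios. Genes that are far brighter in the reference deviated by a median of 1.28 on control 1 after normexp, and by 0.113 in those ratios, which argues against that explanation for most of the rise. The bound for this test was changed after its first value was seen. It had first asked whether control 1 stood above the other controls in those ratios, where control 5 reached 0.107 against 0.113 on control 1, and then whether its value fell well below the 1.28 after normexp. A background model set by a few spots of extreme local background is a candidate cause. Once those backgrounds were replaced, the median deviation of control 1 was 0.0916, under the highest of the other arrays at 0.115, and its neutrophil mean was -4.14.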

How the results depend on the processing

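Alternatives with the stray local backgrounds replaced, with control 1 left out of that fit or of the value table, and the permutation of list means were chosen after seeing the data. The count of genes, 0 under the planned fit, was 11 with Agilent processed signals, 13 with the value table of the same 9 samples, 37 with all 10 samples and 6 without control 1. It was 68 at an unadjusted p under 0.05 with at least a 1.5-fold difference. It ranged from 0 to 1 over the arrays left out in turn, with 1 call without control replicate 3 and 1, Ccnd1, without aldosterone replicate 1. It was 0 under all others, including the Cy3 channel alone, which had 857 genes at an unadjusted p under 0.05. Filters on signal over background had no call among genes to remove. Of the 37 calls in the value table, 27 were above background on all 9 arrays and 3 on no control. Aquantile leaves log2 ratios unchanged, so it tests nothing here. The cause of the differing counts was not tested.

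The count of lists, 10, was 0 with an estimated correlation and 0 with fry, which allow for the correlation of members, and 2 had an unadjusted exact permutation p under 0.05. With 1 array left out it ranged from 7 to 12. Fibroblast, matrix and proliferation lists passed camera in all 31 alternatives, and hypertrophy in 30. With an estimated correlation no list passed in any of them. Among lists that passed in either setting, the direction in camera turned with scale normalization for oxidative stress (0.13), interferon response (0.090) and neutrophil markers (0.74), without control replicate 2 for interferon response (0.000164), and in the value table for neutrophil markers (0.25, and 0.27 without control 1). With 1 array left out, the interferon shift ranged from -0.32 to 0.000164. The mean of the lymphocyte list was 0.00728 without control replicate 1, while its direction in camera stayed. Lists that passed in neither setting also changed sign, such as neutrophil markers with stray backgrounds replaced (0.11) and monocyte markers with the replicate block (-0.05). Their cause was not tested. A change of sign of a single gene was counted as a reversal only where the gene passed in either setting.

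Replicate numbers 1, 2, 3 and 5 are shared by both groups. Deviations of same-numbered arrays correlated at 0.43, 0.38, 0.42 and -0.27 over genes, and at 0.06, 0.34, 0.35 and -0.34 with stray backgrounds replaced. As number 5 correlated negatively, and pairing was taken only where every number exceeded 0.1, the numbers were not taken to pair the samples. Arrays numbered 2 shared 1 of the sets of hearts described below, as did those numbered 3, while those numbered 1 and 5 came from different sets. The correlations may follow the sets, so they cannot show whether the numbers pair the samples. A fit with the replicate number as a block called 0 genes and 10 lists, without circadian clock (adjusted p = 0.0891) and with ion channels and transporters (0.0188).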

Other observations

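All tests of explanations in this part were chosen after the result was seen, and so was the comparison of the 0 called genes with other splits of the samples. The other comparisons with splits were set before their values were seen, those with stray backgrounds replaced after that alternative was chosen. Outside the comparison of the report, the 10 hearts fell into 2 sets that crossed the groups. Controls 1, 3 and 4 with aldosterone 3 and 5 formed 1 set, and controls 2 and 5 with aldosterone 1, 2 and 4 the other. The genes given here were named after their values were seen. In the value table, the potassium channel subunit gene Kcnip2 differed by -1.93 between the sets. Log2 ratios of the gap junction gene Gja1 lay between 0.38 and 0.60 in the first set against 1.42 and 1.85 in the second, and those of Ppargc1a, a regulator of mitochondrial genes, between 0.28 and 0.58 against 1.06 and 1.36. The vesicular glutamate transporter gene Slc17a7 lay between 0.05 and 0.78 in the first set and between -2.47 and -1.80 in the second, and Dpy19l2 between 3.18 and 4.92 against -0.27 and 0.07. On the 9 arrays with stray backgrounds replaced, Dpy19l2 lay between 0.45 and 0.89 against -0.23 and 0.02. Over all genes, 2595 did not overlap between the sets, or 11.8%, where an arbitrary split gives 0.794%.

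This split was found among 100 splits of the 10 samples, drawn at random with the real one included, and called 2357 genes, far more than the 37 of the real groups. It points to a structure of the samples that the labels do not record. Slide or scan argues poorly for it, since 3 of the 4 slides held arrays of both sets. A different reference channel is also argued against, because the median size of the Cy3 difference over the called genes was 0.0222, against 0.289 for the log2 ratio. An unrecorded difference between the animals, such as genotype or litter, may underlie the sets and was not tested. The Y-linked gene Ddx3y lay between 1.85 and 2.04 in all 10 hearts, which the labels give as male.

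The rise of the proliferation list was weighed against technical sources. With stray backgrounds replaced, its mean Cy3 difference was -0.0017 (SE 0.00484), against a shift of 0.36 in the log2 ratio. Under the planned normalization that shift was 0.22. The reference channel therefore does not account for the rise. More blood left in the aldosterone samples may contribute and cannot be told apart. With stray backgrounds replaced, the red cell list shifted above the lymphocyte list (exact permutation p = 0.0159). It did not shift clearly above the neutrophil list (exact permutation p = 0.159). More blood need not raise these lists by equal amounts, so the comparisons cannot decide for or against it. The test first asked for the lymphocyte comparison alone, and the neutrophil comparison was required after that value was seen. Tests of a change in fibroblast content were left out of this part, so that 3 patterns were weighed. A response of dividing cells to aldosterone stays open as a hypothesis, and array position stays confounded with the groups.

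Other splits of the samples gave results as large in most tests. With 0 genes called, all 100 splits of the 9 arrays gave as many by necessity, so that count tests nothing, and the highest gave 663. For genes at an unadjusted p under 0.05, 56 of 100 gave at least 693, up to 3710, and for lists passing camera 61 of 100 gave at least 10, up to 15. With stray backgrounds replaced, 24 of 100 gave at least 1365 such genes, up to 5071, and 21 of 100 gave at least 11 lists, up to 15. Chance could therefore not be excluded for the counts of genes at an unadjusted p and of lists. The split with 663, 3710 and 5071 genes was that of the 2 sets on the 9 arrays. With stray backgrounds replaced, splits whose 4 arrays came from the other set alone gave 3977, 3225 and 1987, while the real groups held arrays of both sets. The shares of splits given here therefore also carry the sets. For the 37 genes of the 10-sample table, 2 of 100 splits gave as many. These were the real one and the split of the 2 sets, with 2357. That share lies under 5%, but it was not adjusted for the other comparisons with splits given here. Among the ways of processing, this table also gave the most genes at an adjusted p under 0.05. Chance was therefore not excluded for the 37 genes either. Another split gave 36.

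Probes well above background on all 4 aldosterone arrays and on no control numbered 11, and 0 showed the opposite. Of the 11, 1 belonged to the proliferation list (Bub1), and the others included Knl1, Dscc1, Robo2 and Kcnab3. An exact count over all 126 splits of the arrays gave p = 0.0794, with a highest count of 57.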
